A study of Arabidopsis thaliana with 8 samples.

How the data were processed

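The measurements were ribosome footprint counts from 8 libraries of Arabidopsis thaliana Col seedlings, 4 from root and 4 from shoot, with 1 library for each tissue and each of 4 polysome extraction buffers. According to the labels, ground tissue was lysed in the buffer, the lysate was treated with RNase, ribosomes were isolated on size exclusion columns, and rRNA was depleted before library construction with a ribosome profiling kit. The authors deposited raw counts per gene on coding sequences, whole numbers without normalization, in a table with 1 column per library. Bowtie2, STAR 2.5.1b and the TAIR10 build are named in the submitters' processing notes, without roles or order. The counting program, the footprint length filter and the treatment of reads that match several places are not given in the sources used here. Reads from near-identical genes, and from mitochondrial loci with copies in the nuclear genome, may therefore be counted at either locus. Footprint length and reading frame cannot be measured from counts on coding sequences and were not analysed here, nor was any RNA-seq library, so a difference in counts combines mRNA level and translation.

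The table held 27416 genes, of which 5509 had a count of 0 in all libraries. Totals ran from 1120218 to 3410266 counts in root and from 3746348 to 4501213 in shoot. Names came from a RefSeq table of the TAIR10.1 assembly, used for names only, which matched 26719 of the 27416 identifiers and 0 of the 210 organelle loci. Organelle loci are named by their identifiers, and genes without a symbol likewise.

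Each library was assigned its tissue and buffer from its title. Counts were analysed in R 4.3.3. The main test was edgeR 4.0.16, with TMM normalization, filterByExpr by tissue (minimum count 10, minimum total count 15), which kept 15664 genes, and the quasi-likelihood F test with tissue and buffer as terms. This left 3 residual degrees of freedom, with the interaction of tissue and buffer as the error. Contrasts were root minus shoot, any of the 4 buffers, buffer A minus C, and buffer D minus B. A model with numeric MgCl2, Tris and the interaction of tissue with MgCl2 tested whether the salt trend differed between tissues, and its coefficients are given per 10 mM MgCl2. KCl was at the same ratio to MgCl2 in all buffers, so this trend is equally one with KCl. Where a left-out library leaves a buffer with 1 library, that library is assumed to vary like the others. The remaining library is then fitted by its own buffer term. For root minus shoot, leaving out either library of a buffer is therefore nearly the same check. P-values were adjusted by Benjamini-Hochberg and called at 0.05. Log2 fold changes are given ± a standard error, taken as their absolute value divided by the square root of F. It is approximate, above all where counts are low. CPM values of genes are scaled by library total and TMM factor, and so are the folds computed from them. Shares of counts, and the CPM behind the correlations between libraries and between buffer ratios, use library totals alone. Where a tissue had 0 counts of a gene, the fold was computed against 3 counts over its 4 libraries and is given as a lower bound.

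Before the data were examined, 23 gene lists with 318 members were fixed, along with the tests, most of the alternatives and the rule for naming genes. They cover photosystem and antenna genes, the Calvin cycle, photorespiration, chlorophyll synthesis, aliphatic glucosinolates, cuticle and wax, shoot meristem, leaf and stomatal regulators, endodermis and suberin, root hair, root meristem and auxin transport, ion uptake, seed storage, lipid mobilisation and the glyoxylate cycle, nitrogen assimilation, the circadian clock, heat shock, touch, wound and cold response, DNA replication and division, secreted wall proteins, plasma membrane and tonoplast proteins, ER chaperones, translation factors and cytosolic ribosomal proteins. Plastid-encoded and mitochondria-encoded genes made 25 lists in all. A planned extension of the ribosomal protein list was not applied, because the reference table held no protein descriptions. Lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and, as an alternative, an estimated correlation, adjusted over the lists. Camera compares a list with all other genes. List tests of the interaction were not among the tests fixed beforehand. No list call in any contrast held with the estimated correlation. Genes were named by rule. For the tissues these were the 10 with the largest fitted fold change in each direction, among genes that passed, had the same sign in all 4 buffers and a mean of at least 10 CPM in the higher tissue. For each buffer test they were the 10 with the smallest p among those that passed, or the 3 with the smallest p where none passed. The 5 highest genes of each tissue and up to 4 members of each list, the highest counts first, completed the rule. Other list members, where named, were chosen after their values were seen, as exceptions within their list. The alternatives were not run for these added genes.

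Shares of counts have exact Clopper-Pearson 95% intervals, ratios of shares have exact intervals conditional on the summed counts, and both cover counting error only. Tissue means of shares and totals were compared by a two-sided exact permutation test of 4 against 4 libraries, whose smallest p is 0.0286. Correlations between libraries used log2(CPM + 1) over tested genes.

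The alternatives were DESeq2 1.42.0 as the test, its size factors in edgeR, no count filter, leaving out organelle-encoded genes, leaving out each library in turn, no buffer term, a numeric MgCl2 trend, robust dispersion, library totals without TMM factors, an estimated correlation in camera, and other pseudocounts, count minimums and gene sets for shares and correlations. Of these, library totals without TMM factors were chosen after seeing the data. So were leaving out the AT2G07 loci, thinning to the smallest library, and correlations of buffer ratios without the AT2G07 loci or with organelle-encoded genes alone. The mitochondria-encoded share within buffers, or without loci higher in shoot, was also chosen then.

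The procedure was tested on negative binomial counts simulated with each gene's mean share, the library sizes and the fitted dispersion trend. The mean share was taken over all 8 libraries and used for both tissues, so the tissue differences of the data were not simulated. Of unchanged simulated genes, 4.50% for any buffer, 4.27% for A minus C and 4.54% for D minus B had an unadjusted p under 0.05 in edgeR. In the data 121, 253 and 312 of 15664 genes did, fewer than the 783 by chance. Recovery in the data may therefore differ from the simulated rates. For root against shoot 26.8% of 97 genes changed by 2-fold and 80.2% of 91 changed by 4-fold were recovered among 14928 genes. For A minus C the values were 8.70% of 92 and 56.0% of 91 among 14946 genes, for D minus B 15.5% of 97 and 46.9% of 96 among 14892, and for any buffer 17.2% of 93 and 58.9% of 90 among 14902. The interaction recovered 0 of 93 genes changed by 2-fold and 7.78% of 90 changed by 4-fold among 14920. Unchanged genes called were 5 for root against shoot, beside 26 and 73 changed genes called, 9 for A minus C, beside 8 and 51, 2 for D minus B, beside 15 and 45, 2 for any buffer, beside 16 and 53, and 0 for the interaction, beside 0 and 7. In a simulation of 20 lists of 30 genes with 1 list raised by 2-fold in buffer D among 14935 genes, camera called that list with the preset correlation (adjusted p = 2.52e-12) and missed it with the estimated one (adjusted p = 0.0735), and it called 0 other lists either way.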

Results

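Ribosome footprints, the short mRNA pieces that translating ribosomes shield from nuclease, were sequenced from roots and shoots of 4-day-old Arabidopsis thaliana Col seedlings harvested 3 h after lights on. Each tissue was extracted in 4 polysome buffers, which gave 8 libraries, 4 from root and 4 from shoot, with 1 library for each tissue and buffer. Buffer A held 50 mM KCl and 25 mM MgCl2, buffer B 40 mM KCl and 20 mM MgCl2, and buffer C 30 mM KCl and 15 mM MgCl2, all in 200 mM Tris. Buffer D had the salts of buffer B in 100 mM Tris. The 4 buffers stood in as repeats of each tissue. Nothing in the labels says that they came from separate plants or cultures, so p-values measured only the spread between these libraries. Counts on coding sequences totalled 3410266, 1646715, 1802349 and 1120218 in the root libraries A, B, C and D, and 4501213, 4253637, 3778810 and 3746348 in the shoot libraries in the same order. The mean shoot total was 2.04 times the mean root total, and all 4 shoot libraries lay above all 4 root libraries (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give). Between 15252 and 17986 genes had a count in a root library, and between 18559 and 19348 in a shoot library.

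The genes with the most footprints differed in part between the tissues, with PYK10 and ATMS1 among the 5 highest in both. These levels are not corrected for the length of the coding sequence, and they combine mRNA level and translation. In root the 5 genes with the highest mean level were PYK10 (AT3G09260), a beta-glucosidase of ER bodies, at 10808 ± 1095 CPM (scaled by library total and TMM factor; mean ± SD, n = 4), ATMS1 (AT5G17920), a methionine synthase, at 8821 ± 721 CPM, HOG1 (AT4G13940), an S-adenosylhomocysteine hydrolase, at 4483 ± 321 CPM, AT5G60390, listed among the translation elongation factors, at 4240 ± 243 CPM, and LOS1 (AT1G56070), a translation elongation factor, at 4090 ± 349 CPM. In shoot the plastid-encoded ATCG00490 led with 22955 ± 3237 CPM. It was followed by RBCS1A (AT1G67090), a small subunit of Rubisco, at 17452 ± 1427 CPM and CAB1 (AT1G29930), an antenna protein, at 11399 ± 574 CPM. PYK10 and ATMS1 completed the list in shoot at 9196 ± 486 and 7772 ± 336 CPM. The 10 highest genes of a library held 5.72 ± 0.239% of root counts and 8.31 ± 0.228% of shoot counts (n = 4 each, two-sided exact permutation p = 0.0286, the smallest possible).

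The comparison of the tissues asked which coding sequences carried more ribosomes in root than in shoot. Photosynthesis, chlorophyll synthesis, the cuticle and leaf regulators were higher in shoot, and root hair, endodermis and ion uptake genes were higher in root. Of 15664 genes tested, 6315 differed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 2781 higher in root and 3534 higher in shoot. At an unadjusted p under 0.05 there were 7398 genes, where 783 would pass by chance. The median log2 fold change of all genes, root minus shoot, was -0.12, and the median standard error of a gene was 0.42. The TMM factors, 1.17 to 1.22 in root and 0.830 to 0.849 in shoot, set this level. With library totals alone the median was 0.38, and 4767 genes were higher in root and 2687 higher in shoot, so the direction of differences of about 0.5 or less depends on the scaling.

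Genes of the photosynthetic machinery fell as a body in root. All 39 measured photosystem and antenna genes were lower in root than in shoot, with a median log2 fold change of -6.51. CAB1 stood at 72.7 ± 8.68 CPM in root and 11399 ± 574 CPM in shoot (log2 fold change -7.30 ± 0.10 SE, adjusted p = 4.2e-11), and CAB2 (AT1G29920) and CAB3 (AT1G29910) had log2 fold changes of -7.70 ± 0.13 and -7.69 ± 0.16. LHB1B2 (AT2G34420), another antenna gene, kept 212 ± 19.3 CPM in root against 5396 ± 583 CPM in shoot (-4.67 ± 0.09). All 39 passed when adjusted over the list alone, and the camera test gave an adjusted p of 1.47e-38 (adjusted p = 0.0919 with an estimated correlation). The Calvin cycle list had 18 of 18 genes lower in root, with the same count adjusted over the list alone and a median of -6.88. RBCS1A had a log2 fold change of -7.80 ± 0.17, RCA (AT2G39730), the Rubisco activase, -6.28 ± 0.10, RBCS3B (AT5G38410) -7.77 ± 0.19 and RBCS2B (AT5G38420) -7.90 ± 0.26. The camera adjusted p of that list was 1.86e-21 (adjusted p = 0.0919 with an estimated correlation). The members that differed least were TIM at -1.72, EMB3119 at -2.32 and AT3G60750 at -2.50. Near-identical copies in the CAB and RBCS families can share reads, so the values of single members are uncertain. Of the 57 genes in both lists, 56 had counts in all 4 root libraries, at a median of 0.925% of the shoot level.

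Photorespiration and chlorophyll synthesis followed. All 12 photorespiration genes were lower in root, also when adjusted over the list alone, with a median of -5.00. GOX1 (AT3G14420), a glycolate oxidase, had 4.24 ± 3.06 CPM in root and 1448 ± 181 CPM in shoot (-8.26 ± 0.33), and SHM1 (AT4G37930), the mitochondrial serine hydroxymethyltransferase, had a log2 fold change of -4.74 ± 0.15. CAT2 (AT4G35090), a catalase, differed less at -2.52 ± 0.10, as did GLDP1 (AT4G33010), a glycine decarboxylase subunit, at -3.49 ± 0.15. The camera adjusted p was 1.73e-13 (adjusted p = 0.0919 with an estimated correlation). All 14 chlorophyll genes were lower in root, also when adjusted over the list alone, with a median of -5.73. GUN5 (AT5G13630), the large subunit of magnesium chelatase, had 5095 ± 77.5 CPM in shoot and 90.6 ± 19.0 CPM in root (-5.84 ± 0.13). CRD1 (AT3G56940) and PORB (AT4G27440), a protochlorophyllide oxidoreductase, had log2 fold changes of -6.38 ± 0.17 and -7.99 ± 0.36, and HEMA1 (AT1G58290), at the start of the pathway, -4.29 ± 0.14. PORA had 0 counts in root and was at least 74.0-fold higher in shoot, where folds of this kind set 3 counts over the 4 libraries of the tissue without counts. Camera gave an adjusted p of 7.44e-13 (adjusted p = 0.0919 with an estimated correlation).

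Genes of the shoot surface and of leaf and stomatal development were higher in shoot. All 14 measured cuticle and wax genes, of 15 in the list, were lower in root, also when adjusted over the list alone, with a median of -4.52. LP1 (AT2G38540), a lipid transfer protein, stood at 1209 ± 94.7 CPM in shoot and 8.67 ± 3.26 CPM in root (-7.21 ± 0.19). The ketoacyl-CoA synthases KCS10 (AT2G26250) and KCS6 (AT1G68530) had log2 fold changes of -5.28 ± 0.22 and -5.62 ± 0.23. In the camera test the adjusted p was 1.87e-09 (adjusted p = 0.0919 with an estimated correlation). Of 18 regulators in the shoot meristem, leaf and stomatal list, 13 were measured and 12 were lower in root, also when adjusted over the list alone; KAN was the exception at -1.42 (adjusted p = 0.113). PDF1 (AT2G42840) and ATML1 (AT4G21750), both of the shoot epidermis, had log2 fold changes of -6.49 ± 0.23 and -5.96 ± 0.33, and TMM (AT1G80080), a receptor-like protein of the stomatal lineage, -5.36 ± 0.76. TMM rested on few root counts, 9.57 CPM in root D against 0 to 1.55 in the others. Its value was -7.43 without root D and -7.44 without shoot D, which are nearly the same check. It was -4.61 without root A and -4.67 without shoot A, again nearly the same check, and the call was kept in each. AFO (AT2G45190), a leaf polarity factor, had 0 counts in root and was at least 98.8-fold higher in shoot. The median was -6.49, or -5.36 with the 6 genes without root counts set at their bounds, and the camera adjusted p was 1.70e-06 (adjusted p = 0.0919 with an estimated correlation).

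Genes of the root surface and endodermis were higher in root. All 7 root hair genes were higher, also when adjusted over the list alone, with a median log2 fold change of 4.57. PRP3 (AT3G62680), a cell wall protein of root hairs, reached 1294 ± 213 CPM in root and 89.3 ± 30.0 CPM in shoot (3.90 ± 0.24). LRX1 (AT1G12040), EXPA18 (AT1G62980) and SHV2 (AT5G49270) had log2 fold changes of 3.87 ± 0.42, 4.82 ± 0.29 and 4.57 ± 0.40. As a list they had a camera adjusted p of 3.07e-06 (adjusted p = 0.149 with an estimated correlation). Of 20 endodermis and suberin genes, 17 were measured, 13 were higher in root and 1 was lower, or 14 and 1 when adjusted over the list alone. ESB1 (AT2G28670), PER64 (AT5G42180) and CASP1 (AT2G36100), all of the Casparian strip, had log2 fold changes of 4.27 ± 0.20, 4.30 ± 0.37 and 4.89 ± 0.31, and RWP1 (AT5G41040), a suberin feruloyl transferase, 2.32 ± 0.23. The lower gene was SCR, a transcription factor of the endodermis and bundle sheath, at -1.41 ± 0.44 (adjusted p = 0.0265), and with library totals alone 14 genes were higher and 0 lower. The list median was 2.97 and the camera adjusted p 1.02e-05 (adjusted p = 0.138 with an estimated correlation).

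Of 13 ion uptake genes, 11 were measured and 10 were higher in root, also when adjusted over the list alone, with a median of 3.88. PHT1;1 (AT5G43350), a phosphate transporter, had 274 ± 41.8 CPM in root and 19.4 ± 7.23 CPM in shoot (3.88 ± 0.23), and SULTR1;2 (AT1G78000), a sulfate transporter, had a log2 fold change of 4.17 ± 0.31. The proton pump HA2 (AT4G30190) and the nitrate transporter NRT1.1 (AT1G12110) were high in both tissues, at 2155 ± 142 and 580 ± 44.3 CPM in root, with log2 fold changes of 0.82 ± 0.08 and 0.86 ± 0.10. FRO2, an iron reductase, had a value of 1.22 (adjusted p = 0.537). The camera adjusted p was 9.18e-08 (adjusted p = 0.138 with an estimated correlation). In the root meristem and auxin list only 2 of 5 genes were measured. EIR1 (AT5G57090), the auxin efflux carrier of root gravitropism, was higher in root by 5.36 ± 0.30, and AUX1 (AT2G38120), an auxin influx carrier, had a value of 0.08 (adjusted p = 0.720). That list had 1 gene higher and 0 lower, over all genes and when adjusted over the list alone, a median of 2.72 and a camera adjusted p of 0.162. With library totals alone 2 genes of the list were higher and 0 lower, so the call of AUX1 depends on the scaling.

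In the lipid mobilisation and glyoxylate list 6 of 7 genes were lower in root, also when adjusted over the list alone, with a median of -1.61. ICL (AT3G21720), isocitrate lyase, had 3331 ± 534 CPM in shoot and 49.9 ± 15.7 CPM in root (-6.10 ± 0.13), and MLS (AT5G03860), malate synthase, had a log2 fold change of -4.72 ± 0.18. PCK1 (AT4G37870) and PKT3 (AT2G33150) were lower by smaller amounts, at -1.57 ± 0.13 and -1.38 ± 0.12. Camera gave an adjusted p of 4.65e-06 (adjusted p = 0.0984 with an estimated correlation). Of 13 seed storage genes 2 were measured, the cruciferins CRA1 (AT5G44120) and CRU3 (AT4G28520). Both had 0 counts in root, both passed the test over all genes and when adjusted over the list alone, and they were at least 141-fold and 71.6-fold higher in shoot. Their median was -9.19, or -6.65 at the bounds, and the camera adjusted p was 0.0185 (adjusted p = 0.203 with an estimated correlation). Of 6 nitrogen assimilation genes 5 were lower in root and 1 was higher, also when adjusted over the list alone, with a median of -1.77. The lower genes included the plastid enzymes GLU1 (AT5G04140), a ferredoxin-dependent glutamate synthase, at -7.90 ± 0.14 and GS2 (AT5G35630), a glutamine synthetase, at -3.70 ± 0.09, and the nitrite reductase NIR1 (AT2G15620), with 513 ± 47.5 CPM in root and 1178 ± 159 CPM in shoot. The higher gene was GLT1 (AT5G53460), the NADH-dependent glutamate synthase, at 0.61 ± 0.08. In the camera test the adjusted p was 1.81e-04 (adjusted p = 0.0919 with an estimated correlation).

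The translation machinery differed by small amounts, whose direction depended on the scaling. With library totals alone 7 cytosolic ribosomal protein genes were higher in root and 3 lower, with a median of 0.06, and 3 translation factors were higher and 0 lower, with a median of 0.19. With TMM factors, of 34 cytosolic ribosomal protein genes 26 were lower in root and 0 higher, or 27 and 0 when adjusted over the list alone, with a median of -0.44. RP1 (AT1G43170) and P40 (AT1G72370) had log2 fold changes of -0.42 ± 0.08 and -0.52 ± 0.09, and with library totals alone 0.08 and -0.03. As a list they had a camera adjusted p of 6.95e-08 (adjusted p = 0.0919 with an estimated correlation). Of 8 translation factors 4 were lower and 0 higher, or 6 and 0 when adjusted over the list alone, with a median of -0.30, and LOS1 had a log2 fold change of -0.36 ± 0.07, or 0.14 with library totals alone. The camera adjusted p was 1.08e-03 (adjusted p = 0.203 with an estimated correlation). Of 8 ER chaperones 5 were higher in root and 0 lower, also when adjusted over the list alone, with a median of 0.34, and with library totals alone all 8 were higher; BIP2 (AT5G42020), an ER-resident chaperone of the heat shock protein family, stood at 0.50 ± 0.09. Camera gave an adjusted p of 3.14e-03 (adjusted p = 0.25 with an estimated correlation). Of 5 measured heat shock genes, from 7 listed, 0 were higher and 2 lower, also when adjusted over the list alone, with a median of -0.41. The lower genes were HSP70 (AT3G12580) at -1.98 ± 0.11 and HSC70-1 (AT5G02500) at -0.27 ± 0.07. With library totals alone HSC70-1 stood at 0.23, and the list had 1 gene higher, 1 lower and a median of 0.08. In the camera test the adjusted p was 0.0380 (adjusted p = 0.196 with an estimated correlation).

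In 6 further lists members moved in both directions or few moved, and the camera test called none of them. Of 12 aliphatic glucosinolate genes 4 were higher in root, 3 were lower and 5 did not pass, with the same counts adjusted over the list alone. IMS2 (AT5G23020) and BCAT4 (AT3G19710), both of methionine chain elongation, were higher in root by 1.84 ± 0.12 and 1.26 ± 0.12, while CYP79F1 was lower at -2.40 ± 0.30. The median of that list was -0.10 and its mean -0.19, whereas the camera direction was upward in root (adjusted p = 0.494). Of 10 measured clock genes, from 11, 3 were higher in root and 2 lower, or 3 and 3 when adjusted over the list alone, with a median of 0.80 and a camera adjusted p of 0.494. The morning genes LHY (AT1G01060) and CCA1 (AT2G46830) were lower in root at -1.96 ± 0.31 and -2.56 ± 0.54, and GI (AT1G22770) was higher, at 67.2 ± 12.2 CPM in root and 29.3 ± 5.09 CPM in shoot. Of 6 measured touch, wound and cold genes, from 13, 4 were higher and 2 lower, with the same counts adjusted over the list alone, a median of 1.15 and a camera adjusted p of 0.251. JAZ1 (AT1G19180) and TCH3 (AT2G41100) were higher by 1.27 ± 0.32 and 1.02 ± 0.23, and TCH4 (AT5G57560) was lower at -4.21 ± 0.82. The value of TCH4 was -5.78 without root D and -5.81 without shoot D, which are nearly the same check. It was -3.49 without root A and -3.54 without shoot A, again nearly the same check, and the call was kept in each. Of 11 DNA replication and division genes 3 were lower and 0 higher, also when adjusted over the list alone, with a median of -0.23 and a camera adjusted p of 0.276, and TSO2 (AT3G27060), a ribonucleotide reductase subunit, had the value -1.64 ± 0.13. Of 13 secreted cell wall genes 4 were higher and 6 lower, or 4 and 7 when adjusted over the list alone, with a median of -0.26 and a camera adjusted p of 0.175. EXT3 (AT1G21310), an extensin, was higher in root by 2.18 ± 0.18, and XTH4 (AT2G06850), a xyloglucan endotransglucosylase, was lower at -3.36 ± 0.17. Of 14 plasma membrane and tonoplast genes 5 were higher and 5 lower, with the same counts adjusted over the list alone, a median of 0.10 and a camera adjusted p of 0.530. With library totals alone the medians of the glucosinolate, DNA replication and secreted wall lists were 0.40, 0.27 and 0.24, opposite in sign, and 9 membrane genes were higher and 3 lower.

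The organelle-encoded genes moved apart. Of 85 measured plastid-encoded genes, from 88, 84 were lower in root and 0 higher, also when adjusted over the list alone, with a median of -5.19. ATCG00490 had a log2 fold change of -7.29 ± 0.17 and ATCG00350 of -6.31 ± 0.26, while ATCG00500 had a value of 0.29 (adjusted p = 0.283), and with library totals alone 1 plastid-encoded gene was higher in root. As a list they had a camera adjusted p of 9.41e-31 (adjusted p = 0.0919 with an estimated correlation). Of 43 measured mitochondria-encoded genes, from 122, 28 were higher in root and 3 lower, or 30 and 3 when adjusted over the list alone, with a median of 1.12. ATMG01360 stood at 1991 ± 1281 CPM in root and 776 ± 299 CPM in shoot (1.25 ± 0.12), and ATMG01190 at 1628 ± 955 and 583 ± 261 CPM (1.42 ± 0.10). The 3 lower loci were ATMG00280 at -7.29 ± 0.28, ATMG00370 at -3.83 ± 0.84 and ATMG01060 at -3.22 ± 0.20. ATMG00280 had the value of the plastid-encoded ATCG00490, and the nuclear AT2G07732 lay near it at -6.82. Whether these loci hold reads of plastid genes was not tested, so they are uncertain as mitochondrial genes lower in root. The camera adjusted p was 1.87e-09 (adjusted p = 0.255 with an estimated correlation).

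**Figure D1:**
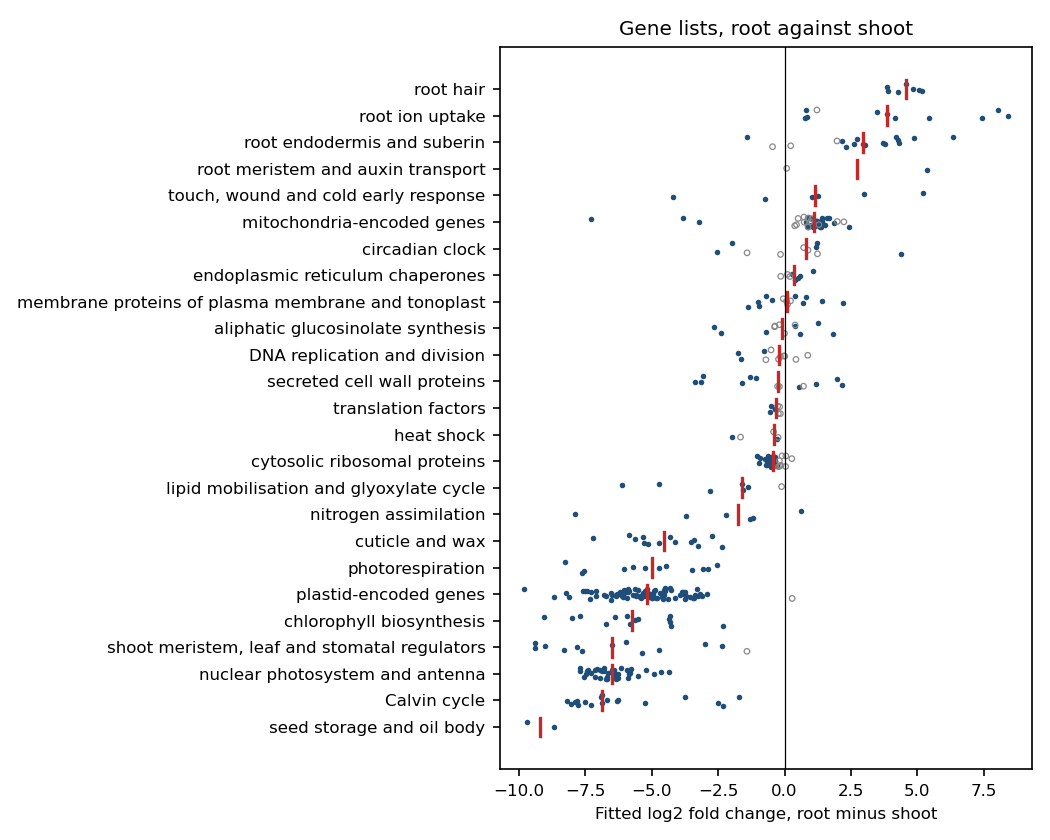
Fitted log2 fold change, root minus shoot (x axis), of every measured gene in the 25 gene lists (y axis); filled points passed the edgeR test at an adjusted p under 0.05, open points did not, and red bars mark list medians. Medians run from 4.57 for root hair genes to -9.19 for seed storage genes, with photosystem and antenna genes at -6.51. The seed storage median rests on 2 genes without root counts and is -6.65 with both at their bounds.

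Among single genes the largest fitted differences were mostly of genes without counts in the other tissue. These were counted among called genes with the same sign in every buffer and a mean of at least 10 CPM in the higher tissue. There were 227 of them, 202 without counts in root. Root libraries had the smaller totals, and how far depth added to the 202 was not tested. On the root side AT2G47540 was at least 136-fold, AT3G59370 at least 131-fold, PGSIP4 (AT1G54940) at least 95.2-fold, AT1G34047 at least 88.7-fold and CPT (AT2G23410) at least 87.9-fold higher in root. AT1G56630, SULTR1;1 (AT4G08620), a sulfate transporter, AT1G05660 and AT5G62330 were at least 78.3-fold, 70.8-fold, 67.9-fold and 66.4-fold higher. BGLU34 (AT1G47600), a myrosinase, was measured in both tissues, at 335 ± 22.2 CPM in root and 0.956 ± 0.83 CPM in shoot (log2 fold change 8.40 ± 0.35, adjusted p = 2.1e-08). On the shoot side LHCB4.3 (AT2G40100), an antenna gene, was at least 422-fold, AT4G28780 at least 405-fold, ARGAH2 (AT4G08870), an arginase, at least 289-fold and AT3G04550 at least 287-fold higher in shoot. OEP6 (AT3G63160), AT5G16030, TGG2 (AT5G25980), a myrosinase, PIFI (AT3G15840), AT3G48200 and AT5G44440 followed at 257-fold, 243-fold, 235-fold, 234-fold, 222-fold and 201-fold or more.

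Extraction buffers were compared to see whether ionic strength or Tris concentration altered which footprints were recovered. The few genes that passed were mitochondria-encoded or, with all 8 libraries, lay in a stretch of chromosome 2 loci. Of 15664 genes 9 differed between the 4 buffers (edgeR), namely the mitochondrial ATMG01190, ATMG00730, ATMG01360, ATMG00220, ATMG01080 and ATMG00070 and the nuclear AT2G07698, AT2G07671 and AT2G07727. Adjusted p ran from 0.0114 for ATMG01190 to 0.0387 for AT2G07727. At an unadjusted p under 0.05 there were 121 genes, fewer than the 783 that would pass by chance. AT2G07698 followed ATMG01190 closely, at 1704 ± 976 against 1628 ± 955 CPM in root and 604 ± 271 against 583 ± 261 CPM in shoot. AT2G07671 lay near ATMG01080, at 634 ± 457 against 652 ± 458 CPM in root and 218 ± 97.8 against 226 ± 95.5 CPM in shoot. AT2G07727 lay near ATMG00220, at 480 ± 309 against 446 ± 262.5 CPM in root and 163 ± 70.2 against 149 ± 64.0 CPM in shoot. The counts of these pairs are uncertain as counts of separate genes. DESeq2 called 32 genes, 23 mitochondria-encoded and 9 in the AT2G07 stretch. The count was 1 without organelle-encoded genes and 0 without these and the AT2G07 loci (85 at an unadjusted p under 0.05). Leaving out root B, root C, root D or shoot B gave 0 genes in edgeR, with 105, 80, 126 and 229 genes at an unadjusted p under 0.05. Leaving out root A or shoot C gave 2, leaving out shoot A gave 11, and leaving out shoot D gave 13, with 1 nuclear gene outside the AT2G07 stretch. Library totals alone gave 14, with 9 mitochondria-encoded genes and 5 in AT2G07.

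Buffer D against buffer B, which differ only in Tris, gave 7 genes, all higher in D. One of the 2 D libraries, root D, had the smallest total, 1120218 counts, and the lowest correlations with the other root libraries (0.838 to 0.856, against 0.888 to 0.911 among those). ATMG01190 rose by 1.34 ± 0.14 on the log2 scale (adjusted p = 0.0118) and AT2G07698 by 1.32 ± 0.13 (adjusted p = 0.0118). The other 5 were ATMG00730 at 1.42 ± 0.18, AT2G07671 at 1.45 ± 0.19, ATMG00220 at 1.302 ± 0.18, ATMG01360 at 1.25 ± 0.17 and AT2G07727 at 1.398 ± 0.19, each with an adjusted p of 0.0498. Of the 43 mitochondria-encoded genes 41 had positive values, with a median of 1.22, and 4 rose over all genes and 28 when adjusted over the list alone. Camera gave an adjusted p of 2.59e-67 (adjusted p = 0.348 with an estimated correlation). Of the plastid-encoded genes, fitted over both tissues, 28 of 85 were positive, 0 passing over all genes or over the list alone, a median of -0.22 and a camera adjusted p of 5.32e-07 (adjusted p = 0.348 with an estimated correlation). Of 14 plasma membrane and tonoplast genes 2 were positive and 0 passed, also when adjusted over the list alone, with a median of -0.15 and a camera adjusted p of 3.35e-05 (adjusted p = 0.437 with an estimated correlation). The camera test also called 4 lists of which 0 genes passed, also when adjusted over the list alone. These were Calvin cycle (downward, adjusted p = 1.26e-08), photorespiration (downward, 1.26e-03), photosystem and antenna (downward, 0.0178) and seed storage (upward, 0.0178), each with an adjusted p = 0.348 with an estimated correlation. The Calvin cycle median was 0.15 and its mean 0.12, against the camera direction, and the photosystem median was -0.03 and its mean 0.01. In all, 312 genes had an unadjusted p under 0.05, fewer than the 783 that would pass by chance. DESeq2 called 18 genes, 13 mitochondria-encoded and 5 in AT2G07. DESeq2's size factors in the edgeR fit left 2 genes. The count was 1 without organelle-encoded genes and 0 without these and the AT2G07 loci (279 at an unadjusted p under 0.05). It was 0 without root B, root C, root D or shoot B (215, 237, 192 and 732 at an unadjusted p under 0.05), 2 without root A or shoot C, and 17 without shoot D, 16 of them higher in D and 3 of them nuclear genes outside the AT2G07 stretch.

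Buffers A and C span the salt range at constant Tris. Organelle-encoded genes lay higher in A, but no single gene passed. For mitochondria-encoded genes 37 of 43 values were positive with a median log2 fold change, A minus C, of 0.79, and 0 passed over all genes and 21 rose when adjusted over the list alone. In the camera test the adjusted p was 1.61e-26 (adjusted p = 0.244 with an estimated correlation). For plastid-encoded genes 67 of 85 values were positive with a median of 0.35, and 0 passed over all genes or when adjusted over the list alone. As a list they had a camera adjusted p of 4.54e-37 (adjusted p = 0.142 with an estimated correlation). The 7 lipid mobilisation genes had 1 positive value, a median of -0.10 and 1 gene lower when adjusted over the list alone, with a camera adjusted p of 1.00e-05 (adjusted p = 0.142 with an estimated correlation). The camera test also called 5 lists of which 0 genes passed, also when adjusted over the list alone. Photosystem and antenna genes had a median of 0.07 (adjusted p = 2.60e-04, or adjusted p = 0.142 with an estimated correlation) and cytosolic ribosomal proteins of -0.10 (adjusted p = 2.12e-03, or adjusted p = 0.168 with an estimated correlation). Heat shock genes had a median of -0.27 (adjusted p = 2.74e-03, or adjusted p = 0.201 with an estimated correlation), translation factors of -0.13 (adjusted p = 4.87e-03, or adjusted p = 0.449 with an estimated correlation) and the 2 seed storage genes of -1.68 (adjusted p = 3.98e-03, or adjusted p = 0.244 with an estimated correlation). Over all genes edgeR called 0, with a median standard error of 0.57, and DESeq2 called 0. At an unadjusted p under 0.05 there were 253 genes in edgeR and 282 in DESeq2, where 783 would pass by chance. The genes with the smallest p, none of which passed, were ATMG00160 at 1.02 ± 0.20, ATMG00650 at 1.202 ± 0.24 and ATMG00060 at 1.23 ± 0.24 (adjusted p = 1.00 each).

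**Figure D2:**
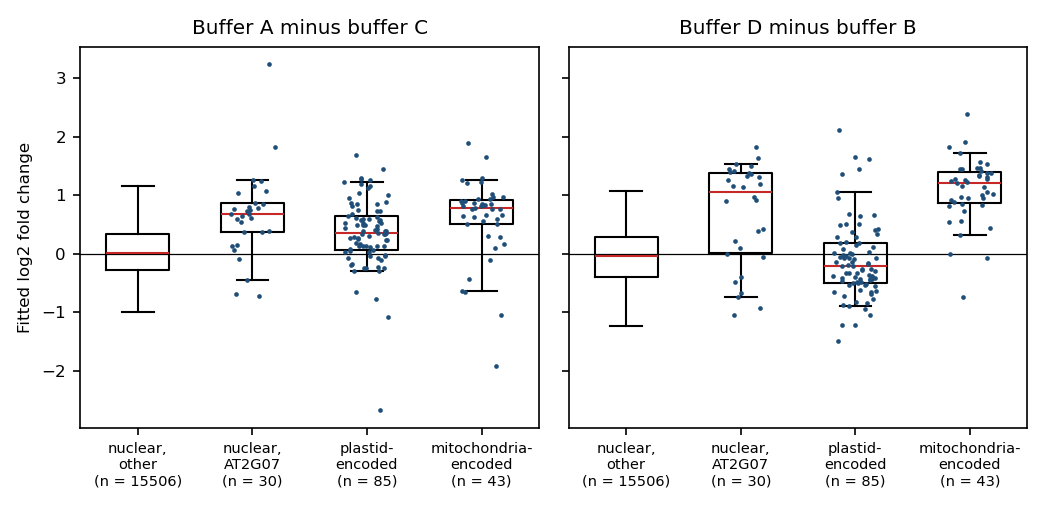
Fitted log2 fold changes (y axis) for buffer A minus C and buffer D minus B by gene class (x axis); points are genes, boxes span the quartiles with the median in red, and whiskers reach the 5th and 95th percentiles. Mitochondria-encoded genes have medians of 0.79 and 1.22, plastid-encoded genes 0.35 and -0.22.

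Whether the salt trend differed between root and shoot was tested as an interaction of tissue with MgCl2, which cannot be separated from KCl because both change in a fixed ratio over these buffers. No gene passed in edgeR, with 618 at an unadjusted p under 0.05, nor in DESeq2, with 596, where 783 would pass by chance. Leaving out shoot C gave 7 genes, all nuclear and outside the AT2G07 stretch, and testing without the low-count filter gave 2. Ion uptake genes had 10 of 11 positive values, a trend per 10 mM MgCl2 more positive in root, with a median of 0.79 and a camera adjusted p of 0.0231. Translation factors had 3 of 8 positive values and a median of -0.29 (adjusted p = 4.44e-05), and plastid-encoded genes 21 of 85 and a median of -0.93 (adjusted p = 1.19e-03). In each of these 3 lists 0 genes passed, also when adjusted over the list alone, and each had an adjusted p = 0.888 with an estimated correlation. Some members had almost no counts in 1 tissue, where a trend cannot be measured. In shoot SULTR1;1 and IRT1 (AT4G19690) had 0 counts and HAK5 (AT4G13420) had 3. Of the plastid-encoded genes in root, ATCG00690 and ATCG01070 had 0 counts, ATCG00550 had 1, ATCG00820 had 2 and ATCG00790 had 3. Others had few, such as ATCG00510 with 4 in root A and 0 elsewhere in root. How far such genes set the plastid-encoded median of -0.93 was not tested. The genes with the smallest p, none of which passed, were SVL2 (AT1G66970) at -3.60 ± 0.65, AT5G38520 at -10.91 ± 1.79 and PCB2 (AT5G18660) at 7.78 ± 1.43 per 10 mM MgCl2 (adjusted p = 1.00 each). AT5G38520 and PCB2 averaged 1.67 and 1.64 CPM in root. Without root C the value of AT5G38520 was -0.29, and that of PCB2 went from 5.71 without root A to 10.97 without root D.

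Summed over genes, the organelle classes took shares of the counts that varied with tissue and buffer. Plastid-encoded genes held 4.41 ± 0.746% of shoot counts and 0.106 ± 0.0253% of root counts (mean ± SD, n = 4 each), a 41.5-fold difference (two-sided exact permutation p = 0.0286, the smallest possible). Without the 10 genes with the highest total they held 2.70% of the remaining shoot counts and 0.0926% of the remaining root counts, a 29.2-fold difference. Mitochondria-encoded genes held 1.16 ± 0.749% of root counts and 0.484 ± 0.121% of shoot counts, and with 1 root library inside the shoot range the difference did not pass (two-sided exact permutation p = 0.0571, n = 4 each). Within buffers root was higher in all 4, by a mean log2 ratio of 1.11 ± 0.49 SD (95% t interval 0.33 to 1.89), a comparison chosen after the values were seen, whose two-sided exact permutation p of 0.125 is the smallest that 4 pairs can give. Without the 3 mitochondria-encoded loci that were higher in shoot, themselves chosen by their direction, the two-sided exact permutation p was 0.0286. In root the mitochondria-encoded share was 2.25% in buffer D (exact Clopper-Pearson 95% interval 2.23 to 2.28), 1.04% in A (1.03 to 1.05), 0.772% in B (0.759 to 0.786) and 0.593% in C (0.581 to 0.604). In shoot the same order held, with 0.636% in D (0.628 to 0.644), 0.516% in A (0.509 to 0.522), 0.427% in B (0.421 to 0.433) and 0.355% in C (0.349 to 0.361). The share in D was 2.92 times that in B in root (95% interval 2.86 to 2.98) and 1.49 times in shoot (1.46 to 1.52), and the share in A was 1.76 times that in C in root (1.72 to 1.79) and 1.45 times in shoot (1.42 to 1.48). The plastid-encoded share in A was 1.44 times that in C in shoot (1.43 to 1.45) and 1.099 times in root (1.03 to 1.17). From B to D it changed by a factor of 0.878 in shoot (0.872 to 0.883) and of 1.499 in root (1.397 to 1.61). These intervals cover counting error only, and the shares of the buffers were compared as values, without a test.

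**Figure D3:**
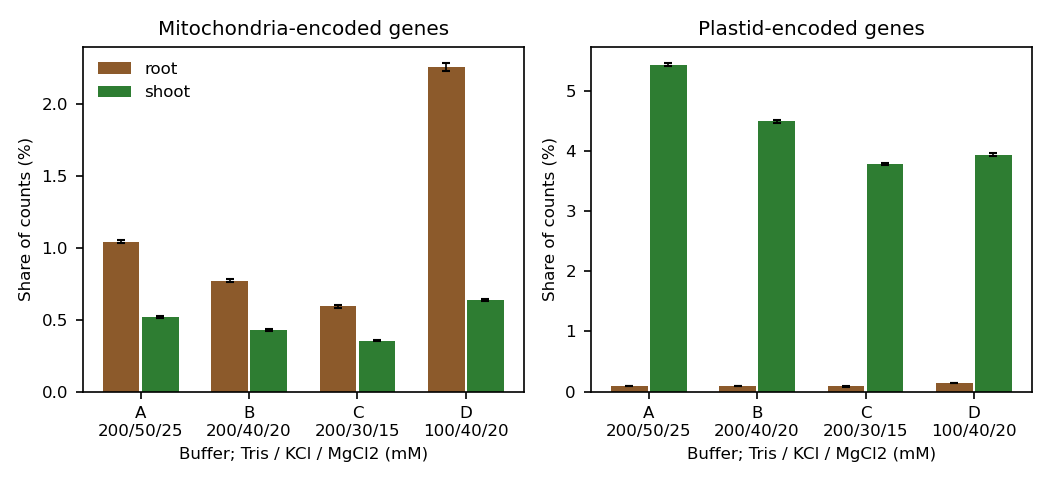
Share of all counts in percent (y axis) on mitochondria-encoded and plastid-encoded genes, for root and shoot libraries in each buffer (x axis); bars are single libraries and error bars exact 95% intervals for counting error. The mitochondria-encoded share was highest in buffer D, at 2.25% in root and 0.636% in shoot, and the plastid-encoded share in shoot ran from 3.78% in C to 5.43% in A.

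Libraries of the same tissue resembled each other more than libraries of the same buffer. Across the 15664 genes, which are not independent replicates, log2(CPM + 1) had a mean Pearson correlation of 0.957 over the 6 shoot pairs (range 0.952 to 0.961), 0.873 over the 6 root pairs (0.838 to 0.911) and 0.504 over the 16 root and shoot pairs (0.479 to 0.529). Mean Spearman correlations were 0.95, 0.876 and 0.518. The mean chi-square per gene with at least 20 counts in a pair was 5.57 for shoot pairs (4.52 to 6.56) and 7.46 for root pairs (5.88 to 8.84), against 0.973 for 2 random parts of 1 library. That comparison covers counting error only, and the pairs differed by more than it. Root D stood apart from the other root libraries, with correlations of 0.838 to 0.856 against 0.888 to 0.911 among the other 3, and of 0.822 to 0.839 against 0.864 to 0.884 with all libraries thinned to the smallest total.

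**Figure D4:**
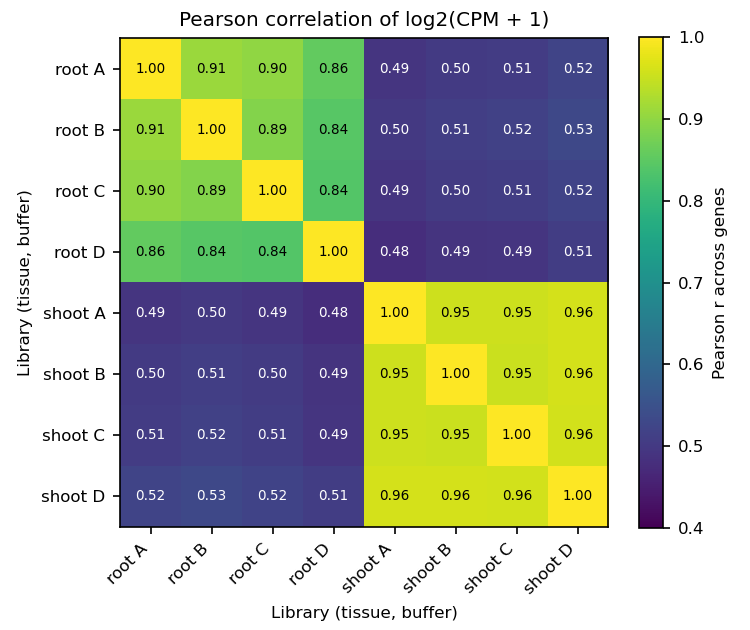
Pearson correlation across genes of log2(CPM + 1) for each pair of the 8 libraries, with tissue and buffer on both axes and the colour scale giving r. Shoot pairs lie between 0.952 and 0.961, root pairs between 0.838 and 0.911 and mixed pairs between 0.479 and 0.529.

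For nuclear genes the ratios between buffer libraries in root were barely correlated with those in shoot. Over 8195 genes with a mean count of at least 50, the log2 ratio of A to C in root had a Pearson correlation of 0.0324 with the same ratio in shoot (Spearman 0.0323), and the ratio of D to B one of 0.0465 (Spearman 0.0394). At a mean count of at least 200 the Pearson values were 0.0597 and 0.0975. At a mean count of at least 50 they were 0.0223 and 0.0312 with nuclear genes alone, and 0.257 and 0.478 with the 102 organelle-encoded genes alone. The standard deviation of the D over B log2 ratio was 0.92 in root and 0.39 in shoot. Each ratio compared single libraries, whose variation lowers such correlations by an amount that was not measured. The mean count was over both tissues, so genes with 0 counts in root, such as LHCB4.3, could enter. The low values therefore do not show that buffer effects differ between the tissues. Genes are not independent replicates, so no p-value was computed for these correlations.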

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

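The tests of technical explanations in this part, depth, preparations, organelle response, shared reads and carry-over, were chosen only after the result was seen, and the list tests of the interaction were not among the tests fixed beforehand. Chance flags about 1 in 20 groups, and of 252 groups of 4 libraries 12 held a library far from the others, where about 13 were expected by chance. The split of the 8 libraries into root and shoot gave 7019 genes without the buffer term, and 1 of 35 splits into 4 and 4, the real one, reached that count, with 0 genes as the highest count of any other. Every other split had root and shoot libraries in both groups, so the difference of the tissues widened its spread. Their count of 0 follows from this, and the splits cannot show how many genes chance would give.

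The mitochondria-encoded share was higher in buffer D than in B and fell from A to C in both tissues. Variation between single preparations stayed open: both tissues gave 1 order of the 4 buffers, a chance of 0.0417, but 2 series of 4 cannot give a smaller one. The D minus B value of ATMG01190 (1.34, adjusted p = 0.0118 in edgeR) stayed at 1.33, 1.34, 1.18 and 1.39 without root B, root C, root D or shoot B. Buffer C does not enter this contrast, so the value without root C could hardly move. The call was lost in these fits, and the reason was not tested. Every fit with 1 library left out had 1 residual degree of freedom fewer, also those that kept calls for D minus B. With 1 library for each tissue and buffer, depth stayed open as well, where shoot D had 1.79 times the share of shoot C at 0.991 times its total, and root B had 1.303 times the share of root C at 0.914 times its total, while in shoot totals and shares both fell from A to B to C. A response common to all organelle ribosomes also stayed open, with the plastid-encoded share in D at 0.878 times that in B in shoot and 1.499 times in root. No biological explanation was tested.

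The nuclear loci called between buffers with all 8 libraries all lay in the AT2G07 stretch of chromosome 2. Reads shared with mitochondrial loci could produce these calls. The buffer profiles of the 30 AT2G07 loci that were tested, of 93 in the table, had a median correlation of 0.866 with the summed mitochondrial profile, above the 95th percentile of 0.201 from 10000 random sets of nuclear genes. Of the 30, 14 lay over 0.9 and 7 were negative, down to -0.81. This is consistent with shared reads at part of the loci, how reads with several matches were treated is not given in the sources used here, and no biological explanation was tested.

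Photosynthesis genes had counts in root. Carry-over of shoot material as the only source stayed open, because the profile of carried-over material was not measured. With the profile of the whole shoot, 1 carry-over level would leave few genes above the lowest upper bound of any gene, and 80.7% of the genes, 46 of 57, lay above it by counting error. That bound, from RBCS1B, was 0.416% of the shoot level, against a median ratio of 0.925% and a highest of 29.5%; reads shared with its copies may shift it, and LHCB4.3, outside these lists and at least 422-fold higher in shoot, would set a lower one. Carry-over as a part of the signal stayed open as well, and translation of these genes in root cells themselves was not tested apart from it.

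A single library stood far from the other 3 of its tissue in 12 cases. The plastid-encoded share was 0.144% in root D, against 0.0882 to 0.0969% in the other root libraries. AT5G38520 had 6.68 CPM in root C and 0 in the others, PCB2 had 5.81 CPM in root A against 0 to 0.736, and TMM had 9.57 CPM in root D against 0 to 1.55. PIP1B had 1186 CPM in root B against 1337 to 1345, and BIP2 had 1452 CPM in root C against 1234 to 1245. In shoot B, RBCS1A had 19578 CPM against 16581 to 16968 and CYP83A1 had 314 CPM against 279 to 281. In shoot A, PER64 had 1.06 CPM against 7.52 to 8.55 and ICL had 2539 CPM against 3487 to 3653. ATML1 had 116 CPM in shoot C against 126 to 127, and AT3G09630 had 1375 CPM in shoot D against 1258 to 1264.

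The trend with MgCl2, or equally with KCl, differed between the tissues in 3 lists by the camera test, ion uptake (adjusted p = 0.0231), translation factors (adjusted p = 4.44e-05) and plastid-encoded genes (adjusted p = 1.19e-03), each with an adjusted p = 0.888 with an estimated correlation. Ion uptake and plastid-encoded genes with almost no counts in 1 tissue entered these tests. From buffer B to D the plastid-encoded share changed by a factor of 1.499 in root and 0.878 in shoot, opposite directions whose difference was not tested.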

How the results depend on the processing

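Library totals without TMM factors, chosen after seeing the data, gave 4767 genes higher in root and 2687 higher in shoot, 5470 of them shared with the TMM result, and 14 genes for any buffer. By construction it moves most root minus shoot values up by about 0.5. Among named genes 9 changed sign with a call on either side, AT5G60390 (0.34), LOS1 (0.14), HSC70-1 (0.23), PIP1B (0.45), CNX1 (0.35), AT1G07940 (0.27), AT1G07930 (0.32), RP1 (0.0778) and AT3G09630 (0.19). Under the other alternatives 0 named genes did so in the contrasts run for them, and the tissue counts stayed within 1.5 times, with 2107 to 2732 genes higher in root and 3057 to 3454 higher in shoot when 1 library was left out. Counts between buffers did not keep theirs. With 1 library left out, the count for any buffer ran from 0 to 13, for D minus B from 0 to 17 and for the interaction from 0 to 7, while A minus C stayed at 0. A buffer with a left-out library rested on 1 library, assumed to vary like the others. DESeq2 gave 32 genes for any buffer and 18 for D minus B, its size factors in edgeR 2 for D minus B, and no count filter 23, 15 and 2 for any buffer, D minus B and the interaction. Leaving out organelle-encoded genes gave 1 for any buffer and 1 for D minus B, and leaving out the AT2G07 loci as well, an alternative chosen after seeing the data, gave 0 and 0, since the called genes were those removed. With an estimated correlation the lists called went from 18 to 0 for the tissues, from 8 to 0 for A minus C and from 7 to 0 for D minus B. The cause was not tested for the other changes.

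The buffer letters were used as a replicate block. Without the block 3228 genes were higher in root and 3791 higher in shoot. Root and shoot libraries of the same letter had correlations of their deviations of 0.0191, -0.00582, 0.0173 and 0.0173 for A to D, all under 0.1. Pairs of different letters ran from -0.0292 to 0.0133, so the values of A, C and D lay above them by small amounts. For genes with a mean count of at least 50 the same-letter values were -0.00231, 0.0317, 0.0365 and 0.0272, against -0.0278 to 0.0267 for different letters. These differences were not tested. The letter marks the buffer, a factor of the design, and was not taken to mean that samples came from the same plants. Root and shoot of the same letter were compared through the buffer term and, for the mitochondria-encoded share, within buffers.

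The plastid-encoded share in shoot went from 4.41 to 2.70% without the 10 highest genes, and the mitochondria-encoded share in shoot from 0.484 to 0.320% without the loci higher in shoot, an alternative chosen after seeing the data. All 4 root libraries then lay above all 4 shoot libraries (two-sided exact permutation p = 0.0286, against 0.0571 with all loci), but the loci were left out by their own direction. Mean Pearson correlations went from 0.873 to 0.830 for root pairs with a smaller pseudocount, from 0.504 to 0.435 for mixed pairs with that pseudocount and to 0.698 with all detected genes, and from 0.957 to 0.940 and 0.963 for shoot pairs under the same changes. Thinning to the smallest library, chosen after seeing the data, gave 0.922 for shoot pairs, 0.852 for root pairs and 0.491 for mixed pairs, fewer counts being its construction. The correlation of the buffer ratios between tissues went from 0.0324 to 0.0597 for A over C and from 0.0465 to 0.0975 for D over B at a mean count of at least 200, and to 0.257 and 0.478 with organelle-encoded genes alone, chosen after seeing the data. In the simulation, which gave a gene the same mean share in root and shoot, 8.70% of 2-fold changes between A and C were recovered. Recovery in the data may differ.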

Other observations

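The genes in this part were chosen after their values were seen. Of 4 myrosinases picked in this way, which hydrolyse glucosinolates, 2 were lower and 2 higher in root. TGG1 (AT5G26000) had 790 ± 29.7 CPM in shoot and 1.96 ± 2.40 CPM in root (mean ± SD, n = 4; log2 fold change -8.30 ± 0.36), and TGG2 had 0 counts in root. BGLU34 and BGLU35 (AT1G51470) were higher in root, by 8.40 ± 0.35 and 6.84 ± 0.33, with BGLU35 at 317 ± 41.3 CPM in root and 2.79 ± 1.59 CPM in shoot.

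Ferredoxins and their reductases went in both directions. The leaf ferredoxins FD1 (AT1G10960) and FED A (AT1G60950) were lower in root at -4.33 ± 0.16 and -5.75 ± 0.19, and FD3 (AT2G27510) was higher, at 250 ± 22.5 against 94.0 ± 13.4 CPM. Among the ferredoxin-NADP reductases, FNR1 (AT5G66190) and FNR2 (AT1G20020) were lower in root at -5.13 ± 0.21 and -7.15 ± 0.29, and RFNR2 (AT1G30510) was higher by 2.13 ± 0.12. RFNR1 (AT4G05390), named as a root form, was lower in root, at 80.0 ± 6.11 against 274 ± 12.7 CPM. Of the glutamine synthetases, the plastid GS2 was lower in root and the cytosolic GSR2 (AT1G66200) higher, at 1852 ± 85.3 against 435 ± 23.5 CPM. GSR 1 (AT5G37600) was also higher in root, by 0.60 ± 0.12 (adjusted p = 2.12e-03 in edgeR). GLN1.3 (AT3G17820) at -0.19 (adjusted p = 0.323) and GLN1;4 (AT5G16570) at 1.06 (adjusted p = 0.357) did not pass.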
